A study of Mus musculus with 20 samples.

How the data were processed

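Total RNA (input) and RNA bound to EGFP-L10a ribosomes (TRAP) came from the same divided lysates of cultured fetal-liver macrophages, as poly(A)-enriched libraries. There were 5 animals with 4 libraries each, 20 in all, with 2 control and 3 knockout-labelled animals. The labels give the embryonic day as 14.5 in the design and 14.4 in the growth protocol. The processing notes name HISAT, DESeq2 and the GRCm38 genome, without versions or roles.

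Each deposited table holds 1 value per gene and library, which was read as TPM because the values of each library sum to 1000000; how the authors computed TPM from the alignments is not given in the sources used here. Columns of mean log2 ratios of hypoxia to normoxia, deposited for each genotype, equal those computed from the TPM values within 1.78e-15, and 10 columns of ratios per animal in each table were not used. Of 52636 genes per table, 52403 IDs were found in the gene table (version ignored). In each of them, 27 symbols had been turned into dates, of which 26 were named from their ID. TPM hold no read numbers, so the depth is unknown and the precision of a value rests on replicates alone.

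Values were analysed as log2(TPM + 1) for genes with at least 1 TPM in at least 2 libraries (13901 in input, 13522 in TRAP, 14842 jointly). limma 3.58.1 in R 4.3.3 (a linear model with empirical Bayes variances and a mean-variance trend) was fitted with 1 mean per group; input and TRAP had separate fits. Benjamini-Hochberg adjusted p-values under 0.05 counted as passing, two-sided, within each of 15 comparisons. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the plots. Comparisons of TRAP with input used a joint fit of all 20 libraries. This departed from the plan, in which a joint test was foreseen for counts alone and fold changes were otherwise to be set side by side; it was adopted after both tables were seen to hold TPM scaled within each library.

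Groups, comparisons, 28 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. By the rule, Elavl1 came first, then passing genes with the largest changes (up to 8 each way, at least 5 TPM on average, groups not overlapping, clone-like names left out), up to 4 passing members of each list, and Vegfa, Hif1a and Tnf in hypoxia comparisons. Where no member of a called list passed, members with the smallest p in the list's direction were named, which was decided after values were seen.

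The animal numbers pair the libraries. Within an animal, deviations from the group means in normoxia and hypoxia correlated across genes at r = 0.28 in controls and 0.34, 0.76 and 0.42 in KO-84, KO-94 and KO-179 for input, and at 0.23, 0.41, 0.58 and 0.29 for TRAP. The animal as a replicate block was an alternative. Others were quantile normalization, no filter, pseudocounts of 0.1 and 5, limma without the trend, only the libraries compared, fry, and leaving out each animal. Where a control is left out, the lone library of a group is assumed to vary like the other groups. Leaving out the single input libraries of WT-280 in hypoxia and KO-84 in normoxia, and a fit averaged over genotypes and fractions, were added after the data were seen. The pipeline was tested on simulated data with the same designs, in which 200 genes and a list of 24 genes were changed. The shifted list was called in every comparison and an unshifted one in none. Genes were simulated independently of each other and without an animal effect. The simulation therefore cannot check list calls where genes are correlated. No batch is given in the labels.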

Results

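RNA was measured in macrophages grown from the fetal livers of 5 mice whose ribosomes carried the ribosomal protein L10a fused to EGFP. By genotype and animal number in the labels, they are called WT-280 and WT-281, the 2 controls (Csf1r-iCre with HuR +/+) and KO-84, KO-94 and KO-179, the 3 animals labelled as conditional knockouts (Csf1r-iCre with HuR fl/fl), a design meant to remove floxed DNA of Elavl1 in the macrophage lineage. Elavl1 encodes HuR, a protein that binds AU-rich elements in mRNAs. Cells of each animal were kept in normoxia (20% O2) or hypoxia (1% O2) for 18 h. From each lysate, total RNA (input) and the RNA on EGFP-tagged ribosomes (TRAP, translating ribosome affinity purification) were sequenced. This gave 20 libraries, with 2 control and 3 knockout-labelled libraries for each combination of oxygen and fraction. The values were TPM, shares of transcripts that sum to 1000000 in each library, so the sequencing depth is unknown and no counting interval is given. Between 10243 and 12402 genes reached 1 TPM in a library. The most abundant protein-coding transcripts were those of the ferritin heavy chain Fth1 (76106 ± 18476 TPM in input, SD, n = 10) and light chain Ftl1 (31805 ± 9511 TPM). The macrophage transcripts Lyz2 (7239 ± 2247 TPM), encoding lysozyme, and Cd68 (2540 ± 497 TPM), encoding a lysosomal glycoprotein, were abundant in every input library.

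The targeted gene, Elavl1, was not lower in the libraries labelled knockout. In normoxia input, Elavl1 measured 47.3 and 25.9 TPM in the control animals WT-280 and WT-281, and 40.1, 154 and 43.0 TPM in the knockout-labelled animals KO-84, KO-94 and KO-179. In hypoxia input, the controls measured 20.8 and 2.07 TPM and the knockout-labelled animals 29.2, 18.3 and 1.69 TPM. In TRAP, normoxia gave 40.4 and 2.88 TPM in controls and 26.0, 72.1 and 3.99 TPM in the knockout-labelled animals, and hypoxia gave 8.25 and 1.14 TPM against 0.760, 19.6 and 6.00 TPM. The log2 difference between genotypes in normoxia input was 0.86 ± 1.04 (SE; limma adjusted p = 1). It was 0.51 ± 1.04 in hypoxia input (0.909), 0.76 ± 1.31 in normoxia TRAP (0.961) and 0.51 ± 1.31 in hypoxia TRAP (1). The last 3 turned negative when 1 animal was left out: −0.91 without WT-281 and −0.18 without KO-84 in hypoxia input, −0.95 without WT-281 and −0.13 without KO-94 in normoxia TRAP, and −0.55 without WT-281 and −0.34 without KO-94 in hypoxia TRAP. A single value per gene covers all of its exons, and the labels do not say which exons are floxed, so the gene-level value may check nothing about the deletion. The libraries are therefore called knockout-labelled throughout, and every direction between genotypes rests on those labels.

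**Figure D1:**
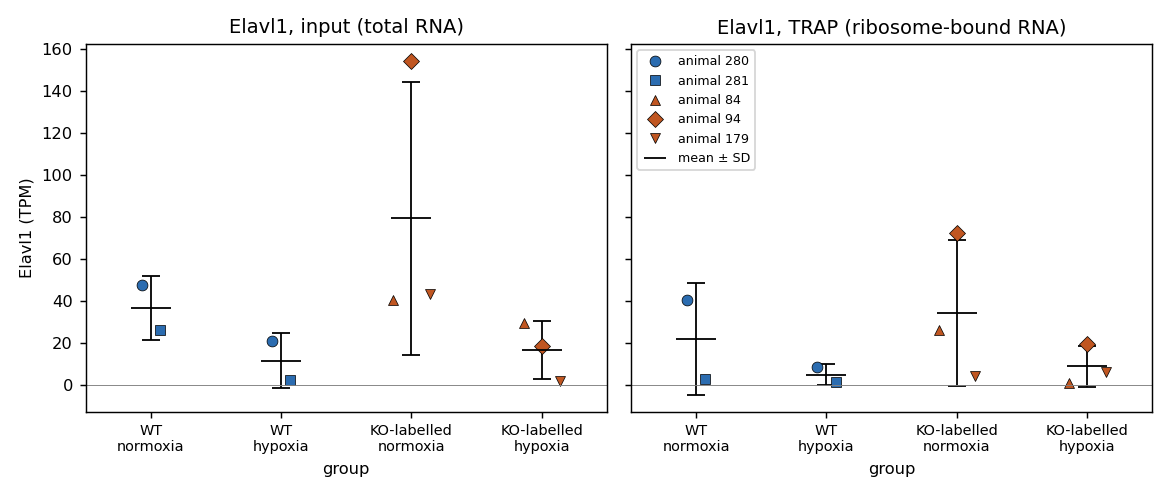
Elavl1 in TPM (y axis) in each library, by group (x axis), for input (left) and TRAP (right); each point is 1 animal, bars give the mean and SD (n = 2 control, n = 3 knockout-labelled). The knockout-labelled normoxia libraries (40.1, 154 and 43.0 TPM in input) do not lie below the control ones (47.3 and 25.9 TPM).

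Several libraries stood apart from others of their group. The control hypoxia input library of animal WT-280 had the fewest genes at 1 TPM or more among the input libraries (10364) and the lowest share of mitochondrially encoded mRNA among them (1.26%). The knockout-labelled normoxia input library of animal KO-84 had the highest such share (4.75%) and listed 15 genes at 0 whose median was at least 20 TPM. The input libraries of animal KO-94 resembled each other more than any other pair did (Pearson's r = 0.980 across genes, which are not independent replicates).

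The first question was which transcripts hypoxia changed in control macrophages, at the level of total RNA. Transcripts induced by the hypoxia-inducible factors (HIF) were more abundant on average in WT-281 (mean log2 change 0.53) but not in WT-280 (−0.06). Immediate early transcripts were less abundant in both. Among 24 HIF targets outside glycolysis, 16 were higher in hypoxia (mean log2 fold change 0.24 ± 0.88, SD over genes), including Ankrd37, an ankyrin-repeat gene induced by HIF (54.8 ± 42.4 against 13.1 ± 11.2 TPM, SD, n = 2 each), and Bnip3, a mitophagy receptor (234 ± 130 against 112 ± 59.4 TPM). Of 20 glycolysis genes, 13 were higher (0.26 ± 0.67), such as Hk1, a hexokinase (6.05 ± 3.99 against 0.397 ± 0.326 TPM). By animal, the mean change of the glycolysis genes was −0.01 in WT-280 and 0.53 in WT-281. All 17 immediate early genes, which report acute stimulation, were lower (−0.95 ± 0.76), among them Fosb (0.124 ± 0.175 against 5.11 ± 0.442 TPM) and the nuclear receptor gene Nr4a1 (0.667 ± 0.943 against 11.9 ± 0.898 TPM). Of 23 targets of the stress factor ATF4, 22 were lower (−0.67 ± 0.47), with Chac1, a glutathione-degrading enzyme, at 8.38 ± 6.44 against 24.7 ± 5.64 TPM. Vegfa, the angiogenic factor, measured 9.02 ± 8.25 against 47.0 ± 19.2 TPM (log2 fold change −2.50 ± 0.844, SE), Tnf −0.84 ± 0.556 and Hif1a −0.35 ± 0.696 (limma adjusted p = 1 for each). With limma, 0 of 13901 genes passed, 445 had an unadjusted p under 0.05 where chance gives 695, and the smallest adjusted p was 0.404. With the animal as a replicate block, 0 passed in limma, with 1501 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0711. By camera, the HIF targets (adjusted p = 0.00306), immediate early genes (0.0101), glycolysis (0.0203), ATF4 targets (0.0363) and the nuclear oxidative phosphorylation genes (0.0363; 22 of 33 higher, 0.06 ± 0.32) differed from other genes. None of the 5 held with an estimated correlation (adjusted p = 0.984 for each), and adjusted over the list alone 1 immediate early gene passed, Fosb. All of these are relative to a median gene at −0.27, or −0.00152 after quantile normalization. Quantile normalization ended the calls of oxidative phosphorylation (0.874) and glycolysis (0.150), as did leaving out the filter (0.104 and 0.0777). A pseudocount of 5 ended that of oxidative phosphorylation (0.0504), and that of ATF4 targets ended with a pseudocount of 0.1 (0.184) and with the compared libraries alone (0.0843). Each call also ended when a control was left out, which leaves 1 library per control group: without animal WT-280 for glycolysis (0.0575), ATF4 targets (0.397), immediate early genes (0.160) and oxidative phosphorylation (0.906), and without animal WT-281 for HIF targets and glycolysis (0.369 each) and for ATF4 targets and immediate early genes (0.138 each). Without the hypoxia library of animal WT-280 alone, glycolysis (0.539) and immediate early genes (0.103) no longer passed, and oxidative phosphorylation (0.937) and ATF4 targets (0.979) changed direction.

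The same question in the knockout-labelled animals gave higher HIF targets and class II antigen-presentation transcripts and lower immediate early transcripts in hypoxia. Of 24 HIF targets, 18 were higher (0.44 ± 0.59), with Ankrd37 at 67.7 ± 3.79 against 22.4 ± 12.1 TPM (SD, n = 3 each). Of 9 tested genes of class II antigen presentation, 8 were higher (0.67 ± 0.85), such as H2-DMa, a peptide-loading chaperone (20.6 ± 3.61 against 7.21 ± 5.46 TPM), H2-Ab1 (4.26 ± 1.15 against 0.532 ± 0.922 TPM) and H2-Aa (2.78 ± 1.34 against 0.115 ± 0.200 TPM). Of 17 immediate early genes, 15 were lower (−0.48 ± 0.45). Of 13 mitochondrially encoded mRNAs, 12 were lower (−0.51 ± 0.35), with mt-Nd1 at 5112 ± 1592 against 8108 ± 4160 TPM. Tfrc, the transferrin receptor, measured 3.88 ± 2.26 against 18.4 ± 8.48 TPM (log2 fold change −2.01 ± 0.599, SE). Vegfa (0.09 ± 0.689), Hif1a (−0.61 ± 0.568) and Tnf (−0.70 ± 0.454) had a limma adjusted p of 1. The limma test gave 0 of 13901 genes past the threshold and 132 had an unadjusted p under 0.05, where chance gives 695; without animal KO-94, 1 gene passed. With the replicate block there were 0 passing in limma and 497 at an unadjusted p under 0.05. Camera called class II antigen presentation (adjusted p = 0.000172; 0.0931 with an estimated correlation), HIF targets (0.00086; 0.335 with an estimated correlation), immediate early genes (0.00156; 0.963 with an estimated correlation), mitochondrially encoded mRNAs (0.0295; 0.963 with an estimated correlation) and the erythroid list (0.0365; 0.335 with an estimated correlation). In that last list only 3 of 15 genes were tested, and Tfrc, which macrophages also express, was the one that passed adjusted over the list alone, as did H2-Aa in its list. The erythroid call was lost with the animal as a replicate block (adjusted p = 0.113), without the filter (0.233), with a pseudocount of 0.1 (0.0957), with the compared libraries alone (0.0573) and without animal KO-94 (0.0623). The mitochondrial call was lost with quantile normalization (0.0531), a pseudocount of 0.1 (0.0688) and without animal KO-84 (0.590), and changed direction without its normoxia library alone (0.534). That library also moved the number of lists called from 5 to 8.

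Whether the hypoxia response of total RNA differed between genotypes was tested as an interaction. No gene or list passed: limma gave 0 of 13901 genes (261 at an unadjusted p under 0.05, smallest adjusted p = 1), and the lowest camera adjusted p was 0.516. The replicate block left 0 in limma, with 891 at an unadjusted p under 0.05. In simulated data for this contrast, 0 of 66 genes changed by 8-fold were recovered, so the test could show no difference of that size. For the control and knockout-labelled hypoxia contrasts of total RNA, 4 and 36 of 66 such genes were recovered. Without the knockout-labelled normoxia library of animal KO-84, 2 lists were called in place of 0.

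**Figure D2:**
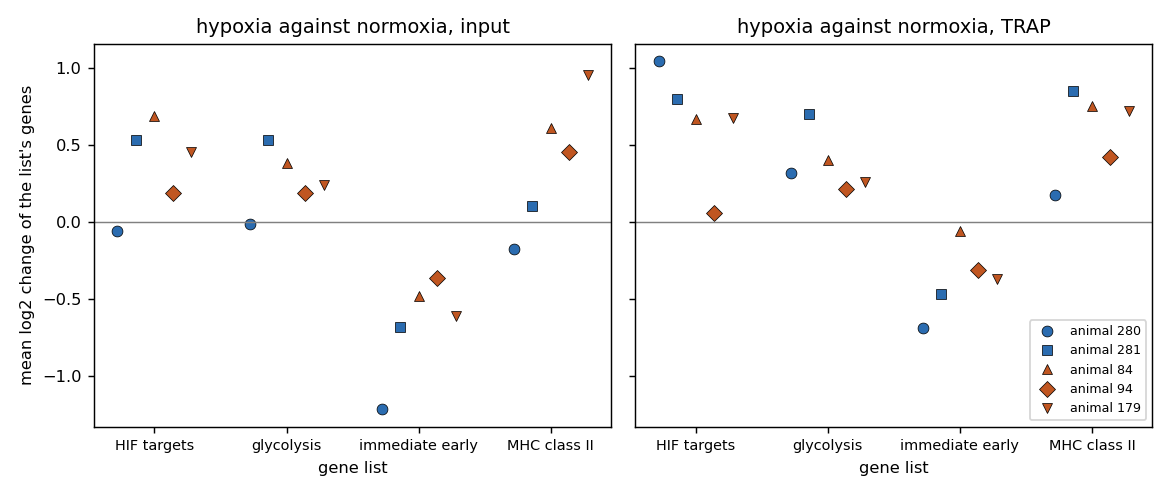
Mean log2 change under hypoxia (y axis) of the genes of 4 lists (x axis) in each animal, in input (left) and TRAP (right); each point is the hypoxia minus the normoxia library of 1 animal. Immediate early genes were lower in all 5 animals in both fractions (input −1.21 to −0.36), and HIF targets were higher in 4 animals in input and in all 5 in TRAP (0.05 to 1.04).

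In the ribosome-bound RNA of control macrophages, HIF targets were more abundant in hypoxia. Of 24 targets, 19 were higher (0.92 ± 1.45): P4ha2, a collagen prolyl hydroxylase, measured 17.9 ± 0.506 TPM in hypoxia and was listed at 0 in both normoxia libraries, Egln3, an oxygen-sensing hydroxylase, measured 15.7 ± 1.18 against 0.272 ± 0.384 TPM (SD, n = 2 each), and Ankrd37 92.1 ± 50.9 against 12.9 ± 7.74 TPM. Of 17 immediate early genes, 14 were lower (−0.58 ± 0.51), including Egr3, a zinc-finger gene (0.506 ± 0.676 against 3.10 ± 0.832 TPM). Hif1a (log2 fold change 1.80 ± 0.923, SE), Vegfa (−0.04 ± 0.597) and Tnf (−1.49 ± 0.769) had a limma adjusted p of 1. In limma, 0 of 13522 genes passed, and 444 had an unadjusted p under 0.05 where chance gives 676; with the animal as a replicate block these numbers were 0 and 1136. Adjusted over the list alone, 3 HIF targets passed. Camera called HIF targets (adjusted p = 0.000259; 0.28 with an estimated correlation) and immediate early genes (0.0283; 0.99 with an estimated correlation). Leaving out animal WT-280 ended both calls (0.0607 and 0.375), and leaving out animal WT-281 ended that of the immediate early genes (0.0775), as did a pseudocount of 0.1 (0.0783). In simulated data for this contrast, 0 of 66 genes changed by 8-fold were recovered.

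In knockout-labelled TRAP libraries, HIF targets and class II antigen-presentation transcripts were higher in hypoxia. Of 24 HIF targets, 17 were higher (0.47 ± 0.56), with Ankrd37 at 84.3 ± 24.7 against 34.7 ± 18.2 TPM (SD, n = 3 each) and P4ha2 at 6.36 ± 0.792 against 3.04 ± 2.66 TPM. Of 9 class II genes, 7 were higher (0.63 ± 0.80), with H2-Aa at 3.13 ± 1.19 against 0.658 ± 1.14 TPM. Vegfa (log2 fold change −0.10 ± 0.487, SE), Hif1a (−0.97 ± 0.754) and Tnf (−0.26 ± 0.628) had a limma adjusted p of 1. Gene by gene, limma gave 0 of 13522 genes past the threshold, and 148 had an unadjusted p under 0.05 where chance gives 676 (0 and 390 with the replicate block). Camera called HIF targets (adjusted p = 0.00832) and class II antigen presentation (0.0178), neither of them with an estimated correlation (adjusted p = 0.326 for each). The class II call was lost with the animal as a replicate block (0.0731) and with a pseudocount of 5 (0.0579). It was also lost without animal KO-84 (0.0549), KO-94 (0.0674) or KO-179 (0.123), and that of HIF targets without animal KO-84 (0.0549) or KO-179 (0.123). The interaction of genotype and oxygen in TRAP gave 0 of 13522 genes with limma (284 at an unadjusted p under 0.05, smallest adjusted p = 0.130; 0 and 751 with the replicate block) and a lowest camera adjusted p of 0.348. Without animal WT-281, 1 list was called. Simulated 8-fold changes were recovered for 7 of 66 genes in the knockout-labelled contrast and for 0 of 66 in the interaction.

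Next, knockout-labelled and control macrophages were compared in normoxia, at the level of total RNA. Inflammatory and fibroblast transcripts were lower and interferon-stimulated, alternative-activation and lysosomal transcripts higher in the knockout-labelled cultures. Of 22 inflammatory genes, 20 were lower (−0.96 ± 0.92), such as the neutrophil-attracting chemokines Cxcl2 (114 ± 87.9 TPM, n = 3, against 482 ± 270 TPM, n = 2, SD) and Cxcl1 (11.4 ± 7.94 against 29.9 ± 3.09 TPM). Of 11 fibroblast genes, 10 were lower (−0.93 ± 0.65), among them Acta2, smooth-muscle actin (102 ± 24.7 against 307 ± 130 TPM). Of 24 interferon-stimulated genes, 19 were higher (0.59 ± 0.69), such as the RNA sensor gene Ddx58 (26.2 ± 3.55 against 9.62 ± 8.44 TPM). Of 12 alternative-activation genes, 10 were higher (0.80 ± 0.93), with the mannose receptor Mrc1 at 147 ± 45.4 against 62.2 ± 6.48 TPM and the folate receptor Folr2 at 226 ± 114 against 69.0 ± 36.9 TPM. Of 24 lysosomal genes, 20 were higher (0.45 ± 0.44). With limma, 0 of 13901 genes passed, 304 had an unadjusted p under 0.05 where chance gives 695, and 19 of 66 simulated 8-fold changes were recovered. Without animal KO-94, 2 genes passed. Camera called the inflammatory (adjusted p = 1.71e-07; 0.132 with an estimated correlation) and fibroblast lists (1.23e-05; 0.622 with an estimated correlation), both of which still passed with any 1 animal left out. The interferon-stimulated (0.000604), alternative-activation (0.00466) and lysosomal (0.0301) calls were lost with an estimated correlation (adjusted p = 0.909 for each). Leaving out 1 animal ended the interferon-stimulated call (0.0829 without WT-281, 0.105 without KO-179), that of alternative activation (0.0829 without WT-281, 0.110 without KO-94) and that of the lysosome (0.426 without WT-280, 0.547 without KO-94). Without animal WT-280 there were 8 calls, and 10 without animal KO-84 or its normoxia input library alone, in place of 5. The median gene lay at 0.11, and at 0.02 after quantile normalization.

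In hypoxia, the same total RNA comparison again had lower inflammatory and fibroblast and higher interferon-stimulated and lysosomal transcripts in the knockout-labelled cultures. Of 22 inflammatory genes, 15 were lower (−0.53 ± 1.07), with the monocyte-attracting chemokine Ccl2 at 1627 ± 1115 TPM (n = 3) against 5111 ± 3892 TPM (n = 2, SD). Of 24 interferon-stimulated genes, 22 were higher (0.89 ± 0.58), such as the interferon regulator Irf7 (97.6 ± 30.2 against 31.6 ± 0.229 TPM) and Oas2, an antiviral synthetase (12.2 ± 6.28 against 2.04 ± 0.221 TPM). Of 24 lysosomal genes, 22 were higher (0.86 ± 0.64). Of 11 fibroblast genes, 9 were lower (−0.34 ± 0.76), with Acta2 at 110 ± 61.3 against 258 ± 39.3 TPM. The limma test gave 0 of 13901 genes past the threshold, although 901 had an unadjusted p under 0.05 where chance gives 695, and 25 of 66 simulated 8-fold changes were recovered. Camera called the inflammatory list (adjusted p = 0.000877; 0.57 with an estimated correlation), and also the interferon-stimulated (0.0053), fibroblast (0.0111), lysosomal (0.0222), oxidative phosphorylation (0.0255) and cell cycle (0.0409) lists. These last 5 had an adjusted p = 0.955 with an estimated correlation. In the cell cycle list the mean (−0.06) and the median (0.02) of 29 genes differed in sign, and 17 of 33 oxidative phosphorylation genes were lower (−0.05 ± 0.55). The median gene itself lay at 0.36, and at 0.00496 after quantile normalization, so list means are to be read against that shift. Quantile normalization ended the oxidative phosphorylation (0.781), cell cycle (0.261) and fibroblast (0.0526) calls, as did leaving out the filter (0.107, 0.143 and 0.0650). A pseudocount of 5 ended those of oxidative phosphorylation (0.0552) and the cell cycle (0.0711), and a pseudocount of 0.1 that of the lysosome (adjusted p = 0.1). Every call ended with 1 animal left out: without WT-281 the inflammatory (0.209), interferon-stimulated (0.336), lysosomal (0.117) and fibroblast (0.456) lists, without KO-94 the inflammatory and lysosomal (0.0601 each), fibroblast (0.384) and oxidative phosphorylation (0.240) lists, without KO-179 the interferon-stimulated list (0.0827), without WT-280 the lysosomal list (0.218), and without KO-84 the cell cycle list (0.833). Oxidative phosphorylation and the cell cycle changed direction without animal WT-280 (0.997 and 0.0929) and without its hypoxia library alone (0.996 and 0.129), and without that library the lysosomal call was lost (0.175). The number of calls fell from 6 to 2 without animal WT-281 and to 3 without animal KO-94.

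**Figure D3:**
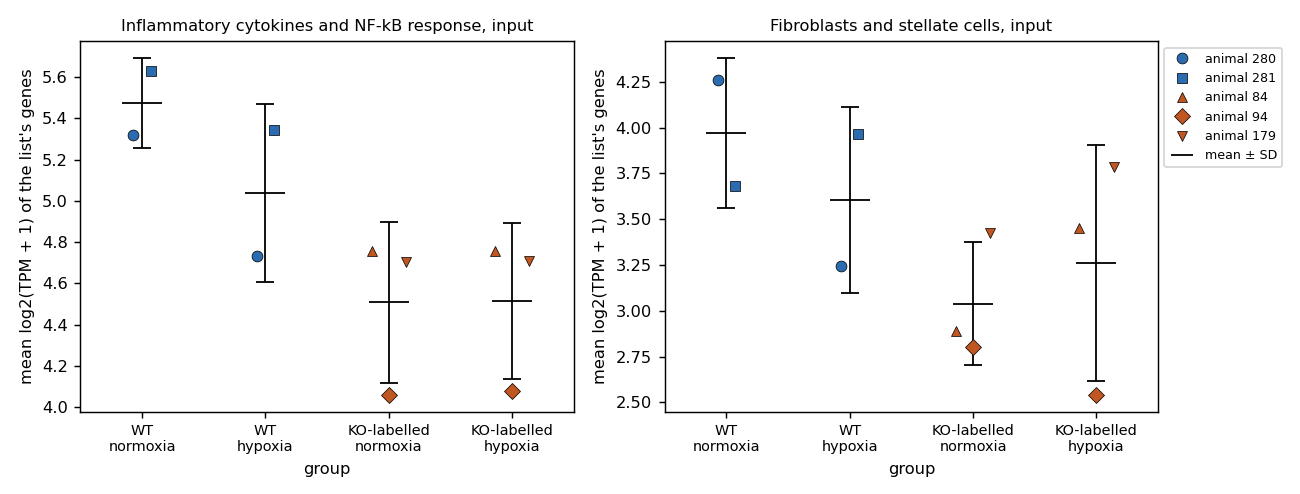
Mean log2(TPM + 1) (y axis) of the inflammatory (left, 22 genes) and fibroblast (right, 11 genes) lists in each input library, by group (x axis); points are animals, bars give the mean and SD. In normoxia the inflammatory list lay at 5.32 and 5.63 in controls and between 4.06 and 4.76 in knockout-labelled animals.

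Genotypes were then compared in the ribosome-bound RNA, in normoxia. Mitochondrially encoded and fibroblast transcripts were lower and ribosomal protein, lysosomal and alternative-activation transcripts higher on average in the knockout-labelled TRAP libraries. All 13 mitochondrially encoded mRNAs were lower (−2.28 ± 1.88), for example mt-Nd2 at 8.40 ± 14.6 TPM (n = 3) against 767 ± 389 TPM (n = 2, SD). All 8 fibroblast genes were lower (−1.60 ± 0.56), with Acta2 at 12.7 ± 9.19 against 55.7 ± 11.8 TPM. Of 41 ribosomal protein and translation factor genes with a 5′ terminal oligopyrimidine (TOP) motif, 39 were higher (0.51 ± 0.29), such as Rplp0 (1578 ± 415 against 882 ± 47.4 TPM). Between libraries, the SE of this mean difference was 0.230. The animals overlapped: ribosomal protein transcripts made up 7.59% of TPM in WT-280 and 10.9% in WT-281. They made up 16.6%, 9.91% and 9.33% in KO-84, KO-94 and KO-179. Of 24 lysosomal genes, 22 were higher (0.79 ± 0.76), and of 12 alternative-activation genes 9 were (0.99 ± 1.18), with the lectin Clec10a at 9.39 ± 2.67 against 0.558 ± 0.790 TPM. In limma, 0 of 13522 genes passed, 704 had an unadjusted p under 0.05 where chance gives 676, and 4 of 66 simulated 8-fold changes were recovered. Without animal WT-280, and without animal KO-179, 1 gene passed.

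Camera called 9 lists in that normoxia TRAP comparison. The mitochondrial (adjusted p = 1.79e-06), fibroblast (2.92e-05), alternative-activation (0.00464), immediate early (0.00746; 14 of 17 lower, −0.56 ± 0.92), inflammatory (0.0193; 14 of 21 lower, −0.76 ± 1.19) and megakaryocyte (0.0438; 4 of 4 tested genes lower, −1.04 ± 0.48) calls had an adjusted p = 0.611 with an estimated correlation. The megakaryocyte gene with the lowest p, the platelet factor Pf4, was among the most abundant transcripts of these macrophage cultures (9922 ± 5233 TPM in input, n = 10). The others were the lysosome (0.00017; 0.69 with an estimated correlation), ribosomal proteins (0.000473; 0.736 with an estimated correlation) and the cell cycle (0.00464; 24 of 29 lower, −0.72 ± 0.98; 0.798 with an estimated correlation). The mitochondrial, fibroblast and lysosomal calls still passed with any 1 animal left out. The others were lost without WT-280 (ribosomal proteins, 0.0511; cell cycle, 0.720 and reversed), WT-281 (inflammatory, 0.445; alternative activation, 0.0880; immediate early, 0.0721; megakaryocytes, 0.575), KO-84 (ribosomal proteins, 0.338; cell cycle, 0.138), KO-94 (inflammatory, 0.437; alternative activation, 0.0649; megakaryocytes, 0.435) or KO-179 (megakaryocytes, 0.145). The megakaryocyte call was also lost with quantile normalization (0.0877), without the filter (0.156) and with a pseudocount of 5 (0.0662), and the inflammatory call without the filter (0.0802) and with a pseudocount of 0.1 (0.0659). Without animal WT-281, 5 lists were called.

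In the TRAP comparison of genotypes in hypoxia, fibroblast and mitochondrially encoded transcripts were lower and ribosomal protein transcripts higher on average. All 8 fibroblast genes (−1.72 ± 0.72) and 12 of 13 mitochondrially encoded mRNAs (−1.76 ± 2.01) were lower in the knockout-labelled libraries, with Acta2 at 13.9 ± 19.4 TPM (n = 3) against 60.3 ± 41.9 TPM (n = 2, SD). Of 41 ribosomal protein and TOP mRNAs, 40 were higher (0.68 ± 0.35), such as Rpl13 (3157 ± 411 against 1510 ± 335 TPM) and Rps6 (1024 ± 141 against 494 ± 77.1 TPM). Between libraries, the SE of this mean difference was 0.396. The animals overlapped: ribosomal protein transcripts made up 4.93% of TPM in WT-280 and 13.7% in WT-281. They made up 16.9%, 10.3% and 10.2% in KO-84, KO-94 and KO-179. The nuclear noncoding RNA Malat1 measured 33.5 ± 34.6 against 426 ± 147 TPM, and 4 of 5 tested nuclear-retained RNAs were lower (−1.71 ± 1.77). Of 33 mRNAs reported as HuR-bound, 22 were lower (−0.49 ± 0.86), including Thbs1, thrombospondin (17.7 ± 13.7 against 70.2 ± 32.5 TPM), and Ccl2 (2578 ± 2684 against 12734 ± 11703 TPM). Ccl2, Cxcl1 and Cxcl2 belong to both this list and the inflammatory list, so the results of these lists are not independent. How far the HuR-bound result rests on shared genes was not tested. Gene by gene, limma gave 0 of 13522 genes past the threshold; 585 had an unadjusted p under 0.05 where chance gives 676, and 14 of 66 simulated 8-fold changes were recovered. Without animal WT-280, 2 genes passed, and 1 without animal WT-281 or KO-179.

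Camera called 8 lists in the hypoxia TRAP comparison. Ribosomal proteins (adjusted p = 6.2e-07) had an adjusted p = 0.686 with an estimated correlation, while the mitochondrial (1.53e-06), fibroblast (1.53e-06), inflammatory (0.0013; 15 of 21 lower, −0.89 ± 1.24) and nuclear-retained (0.00269) lists had 0.469. The rest were the lysosome (0.00148; 20 of 24 higher, 0.67 ± 0.73; 0.726 with an estimated correlation), cell cycle (0.00269; 23 of 29 lower, −0.62 ± 0.73; 0.749 with an estimated correlation) and HuR-bound mRNAs (0.00974; 0.694 with an estimated correlation). Adjusted over the list alone, 1 inflammatory gene, Il1a, encoding interleukin 1 alpha (0.819 ± 0.726 TPM, n = 3, against 9.58 ± 5.66 TPM, n = 2), and 2 nuclear-retained RNAs passed. Only the fibroblast call still passed with any 1 animal left out. Without animal WT-280, ribosomal proteins (0.610), HuR-bound mRNAs (0.254), the lysosome (0.254) and inflammatory genes (0.0612) no longer passed and the cell cycle changed direction (0.325), which left 3 calls. Without WT-281, the mitochondrial (0.305), HuR-bound (0.0748) and nuclear-retained (0.117) calls were lost, without KO-84 that of the cell cycle (0.115) and without KO-94 that of the inflammatory genes (0.187).

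A further comparison asked which transcripts were over- or underrepresented on the tagged ribosomes. TRAP libraries held far less mitochondrially encoded RNA and fewer fibroblast transcripts than input. The mitochondrial rRNA mt-Rnr1 measured 193 ± 237 TPM in TRAP and 4357 ± 2712 TPM in input (SD, n = 10 each; log2 fold change −5.53 ± 0.702, SE; limma adjusted p = 0.000425). The cytochrome c oxidase mRNA mt-Co1 fell by 4.90 ± 0.786 on the log2 scale (0.00321) and mt-Cytb, cytochrome b, by 4.40 ± 0.426 (5.16e-05). Acta2 measured 31.2 ± 29.1 against 176 ± 108 TPM (−2.83 ± 0.423; 0.00141) and the collagen gene Col1a2 10.3 ± 8.56 against 46.3 ± 18.5 TPM (−2.43 ± 0.457; 0.0112). Stromal genes outside the lists, such as Timp1 (−2.41) and Sparc (−2.10), passed as well; they were picked after their values were seen. In all, limma gave 102 of 14842 genes, 97 lower in TRAP, of which 26 had a symbol starting with mt-, and 5 higher: Cdc26 (1.73), Fbxo36 (1.70), Gm43362 (1.06), Ccdc28b (1.02) and CT009757.3 (0.87). The 5 were likewise named after their values were seen. At an unadjusted p under 0.05 there were 1868 genes, and the median gene lay at −0.19 (0.02 after quantile normalization). With the animal as a replicate block, 1104 genes passed and 3541 had an unadjusted p under 0.05. Neither fit models how the difference between TRAP and input varies between animals. Both cultures of an animal count as independent, so the p-values of these fits may be too small. Without the block, the count of 102 became 50, 30, 32 and 55 without animals WT-280, WT-281, KO-84 and KO-179. In simulated data, 64 of 66 genes changed by 8-fold, 50 of 67 by 4-fold and 15 of 67 by 2-fold were recovered. Of the 145 simulated genes called, 14 had not been changed. The joint fit of both fractions departed from the plan, which foresaw it for counts alone; it was chosen once both tables proved to hold TPM scaled within each library.

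Camera called 10 lists between TRAP and input. The mitochondrially encoded mRNAs (13 of 13 lower, −3.93 ± 0.67; adjusted p = 1.36e-28) were the list that held with an estimated correlation (0.0143), and 12 of the 13 passed over all genes and 13 adjusted over the list alone. All 11 fibroblast genes were lower (−1.41 ± 0.91; 1.06e-07; 0.164 with an estimated correlation), 5 past the threshold over all genes and 7 adjusted over the list alone. Of 6 nuclear-retained RNAs, 5 were higher (0.60 ± 0.78; 0.003; 0.164 with an estimated correlation), with Malat1 at a log2 fold change of 2.01 ± 0.514 (SE; limma adjusted p = 0.0907). These 3 calls still passed with any 1 animal left out. Ribosomal proteins (31 of 41 higher, 0.10 ± 0.24; 0.000171), lysosome (22 of 24 lower, −0.49 ± 0.37; 0.00771), glycolysis (19 of 20 lower, −0.52 ± 0.34; 0.0226), endoplasmic reticulum chaperones (17 of 19 lower, −0.42 ± 0.29; 0.023) and cholesterol synthesis (19 of 21 lower, −0.54 ± 0.41; 0.0466) had an adjusted p = 0.753 with an estimated correlation. The cell cycle (29 of 29 lower, −0.68 ± 0.32; 0.0226) had 0.769, and nuclear oxidative phosphorylation genes (21 of 33 higher, 0.03 ± 0.36; 0.0131) had 0.588. Leaving out 1 animal ended the calls of glycolysis (WT-280, 0.217), lysosome (WT-280, 0.0552), cholesterol synthesis (WT-280, 0.0921; WT-281, 0.330; KO-94, 0.0677), oxidative phosphorylation (WT-281, 0.136; KO-94, 0.0539), chaperones (WT-281, 0.305; KO-94, 0.0979), cell cycle (WT-281, 0.118; KO-94, 0.0747; KO-179, 0.0612) and ribosomal proteins (KO-94, 0.0747). The number of calls was 6 without animal WT-281 and 5 without animal KO-94. Quantile normalization ended the calls of oxidative phosphorylation (0.918), ribosomal proteins (0.811) and cholesterol synthesis (0.0527). A pseudocount of 0.1 ended those of glycolysis (0.0637), chaperones and cholesterol synthesis (0.0799 each) and the cell cycle (0.0668), and a pseudocount of 5 that of cholesterol synthesis (0.0643).

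**Figure D4:**
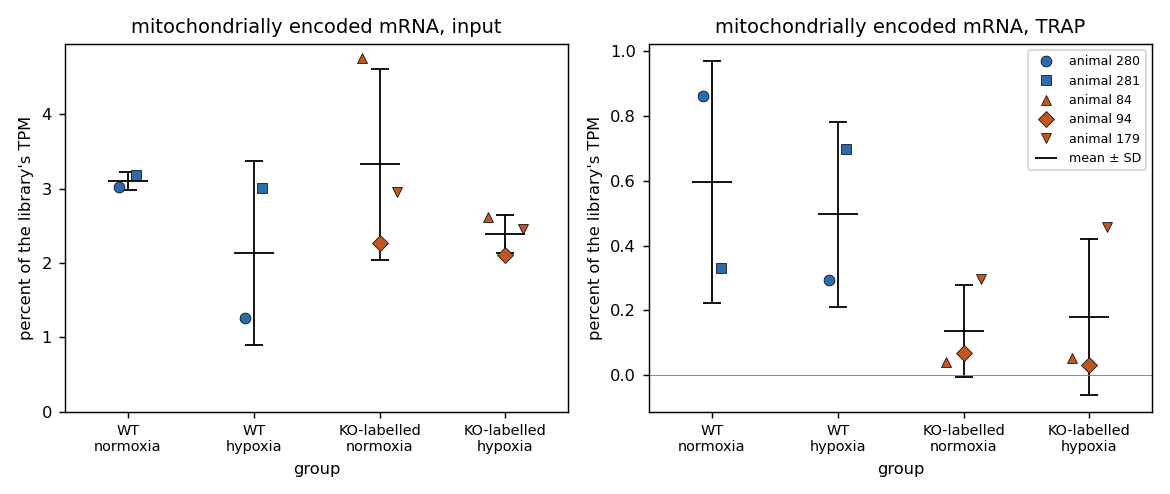
Share of each library's TPM in mitochondrially encoded mRNA (y axis, percent) by group (x axis), in input (left) and TRAP (right, on its own scale); points are animals, bars give the mean and SD. Input libraries ranged from 1.26% to 4.75% and TRAP libraries from 0.0298% to 0.861%.

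The change of the TRAP/input ratio under hypoxia addressed whether hypoxia altered ribosome association beyond RNA level. In controls, limma gave 1 of 14842 genes, 3300002I08Rik, a gene without an assigned function (log2 change 5.67; adjusted p = 0.0284), with 550 genes at an unadjusted p under 0.05 (1 and 1302 with the replicate block). It was at or under 5.02 TPM in all input libraries and listed at 0 in both control normoxia TRAP libraries. Without animal WT-280 the count was 3, and without animal WT-281 it was 0. In knockout-labelled animals 0 genes passed in limma (140 at an unadjusted p under 0.05; 0 and 330 with the replicate block). No list was called in either genotype: the lowest camera adjusted p was 0.493 in controls, for HIF targets (18 of 24 higher, 0.68), and 0.959 in knockout-labelled animals. Without animal KO-94, 1 list was called in the knockout-labelled animals. Simulated 8-fold changes were recovered for 0 of 66 genes in controls and 18 of 66 in the knockout-labelled animals.

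Finally, the TRAP/input ratio was compared between genotypes. Relative to input, ribosomal protein mRNAs were higher and mitochondrially encoded mRNAs lower on average in the TRAP libraries of knockout-labelled cultures. In normoxia, 39 of 41 ribosomal protein and TOP mRNAs were higher (0.56 ± 0.32), such as Rplp0 (log2 difference 0.92 ± 0.483, SE), and 11 of 13 mitochondrially encoded mRNAs lower (−1.78 ± 2.14), such as mt-Cytb (−2.90 ± 1.20). In hypoxia, 35 of 41 ribosomal protein mRNAs were higher (0.35 ± 0.33), and 12 of 13 mitochondrial mRNAs (−1.83 ± 1.80) and 6 of 6 nuclear-retained RNAs (−1.81 ± 1.21) lower, with Malat1 at −3.20 ± 1.45. The animals labelled knockout differed among themselves: the summed mitochondrial TPM in TRAP relative to input was 0.00845, 0.0295 and 0.101 in KO-84, KO-94 and KO-179 in normoxia, against 0.285 and 0.104 in WT-280 and WT-281. In hypoxia it was 0.0200, 0.0142 and 0.187 against 0.235 and 0.232. The Malat1 ratio in normoxia was 2.72, 0.442 and 3.68 against 3.69 and 11.1, and that of fibroblast transcripts 0.128, 0.144 and 0.280 against 0.240 and 0.277. In normoxia KO-179 thus lay at or near the level of a control in each of these, while KO-84 and KO-94 were low also in fibroblast transcripts. The share of ribosomal protein transcripts in normoxia was lower in TRAP than in input in KO-179 (9.33% against 10.1%), as in WT-280 (7.59% against 8.23%). It was higher in TRAP in WT-281 (10.9% against 9.83%), KO-84 (16.6% against 11.2%) and KO-94 (9.91% against 4.73%). With limma, 0 of 14842 genes passed in either condition (376 in normoxia and 441 in hypoxia at an unadjusted p under 0.05; smallest adjusted p = 1 and 0.0531); with the animal as a replicate block or without animal WT-280, 1 gene passed in hypoxia. The block gave 930 genes in normoxia and 1190 in hypoxia at an unadjusted p under 0.05, where chance gives 742. Simulated 8-fold changes were recovered for 3 and 7 of 66 genes. Camera called ribosomal proteins (adjusted p = 1.26e-05) and mitochondrial mRNAs (0.00331) in normoxia, neither with an estimated correlation (adjusted p = 0.991 for each). In hypoxia it called ribosomal proteins (8.58e-05), mitochondrial mRNAs (0.0429; both 0.999 with an estimated correlation) and nuclear-retained RNAs (0.018; 0.526 with an estimated correlation). In normoxia the mitochondrial call was lost without WT-280 (0.709) or KO-84 (0.231) and that of ribosomal proteins without KO-94 (0.137), which left 1 list. In hypoxia, leaving out WT-280 (mitochondrial and ribosomal, 0.476 each), WT-281 (mitochondrial, 0.227; nuclear-retained, 0.0594), KO-84 (mitochondrial, 0.363), KO-94 (mitochondrial and ribosomal, 0.105 each; nuclear-retained, 0.0603) or KO-179 (nuclear-retained, 0.114) ended calls, with 1 list left without WT-280 or WT-281 and 0 without KO-94. The mitochondrial call in hypoxia also ended with the replicate block (0.0787), without the filter (0.0869) and with pseudocounts of 0.1 (0.0754) and 5 (0.162), and that in normoxia with a pseudocount of 5 (0.0628). In hypoxia, quantile normalization ended the ribosomal call (0.0680) and a pseudocount of 0.1 the nuclear-retained call (0.0754). The median gene of the hypoxia comparison lay at −0.25, and at 0.00891 after quantile normalization.

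Lists that passed in no comparison included the macrophage list (15 tested genes, 10 higher in knockout-labelled normoxia TRAP, 0.58; lowest camera adjusted p = 0.128), angiogenic and matrix factors (24 tested, 15 lower in knockout-labelled hypoxia TRAP; 0.176) and AU-rich element binding proteins (17 tested, 14 lower under hypoxia in control input; 0.469). Among markers of other cells, the lowest adjusted p was 0.513 for hepatocytes (6 tested genes), 0.209 for mast cells and basophils (1 tested gene), 0.482 for endothelial cells (4 tested), 0.0953 for dendritic cells and lymphocytes (2 tested) and 0.139 for neutrophils (2 tested). All of these cover the 15 comparisons and not the later fits over 5 animals, in one of which the neutrophil list passed. The HuR-bound list, called in 1 comparison, had an adjusted p of 0.344 between genotypes in normoxia input (21 of 34 lower, −0.12).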

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

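The tests of Malat1 ratios, of inflammatory transcripts in TRAP, of Elavl1 among equally variable genes and of fractions exchanged within whole animals, and the use of the spread of the paired change for ribosomal protein mRNAs, were chosen only after the results were seen.

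Some differences between genotypes in the response to hypoxia stood out. The mean change of 41 ribosomal protein and TOP mRNAs in input was −0.51 and −0.05 in the controls and 0.02, 0.26 and 0.03 in KO-84, KO-94 and KO-179, a difference of 0.38 that was singled out because the animals of each genotype moved in opposite directions. The median gene of that interaction lay at 0.25 as deposited and at −0.00646 after quantile normalization, so much of the 0.38 was shared by genes in general, and the list did not pass (camera interaction adjusted p = 0.516). Hif1a, the oxygen-regulated transcription factor gene, changed on the log2 scale in TRAP by 2.64 and 0.96 in WT-280 and WT-281 and by −1.84, −0.83 and −0.24 in the others, a difference of −2.77 ± 1.19 (SE) singled out in the same way, which did not pass the limma interaction test (adjusted p = 1). The gene 3300002I08Rik passed the test of a changed TRAP/input ratio in controls (5.67): it was listed at 0 in both control hypoxia input libraries, was present in the matching TRAP libraries (8.12 TPM in that of WT-280), and was listed at 0 in all knockout-labelled TRAP libraries. Without WT-281, 0 genes passed in that limma comparison, and without WT-280 3 did.

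The TRAP/input ratio of several lists differed between genotypes by an interaction test. In normoxia camera's adjusted p was 0.00331 for mitochondrially encoded mRNAs and 1.26e-05 for ribosomal protein and TOP mRNAs (0.991 for each with an estimated correlation). In hypoxia it was 0.0429 and 8.58e-05 for these lists (0.999 for each with an estimated correlation) and 0.018 for nuclear-retained RNAs (0.526 with an estimated correlation).

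The first pattern weighed was this difference in TRAP, which in normoxia was not shared by KO-179 in mitochondrial and fibroblast TRAP/input ratios (0.101 and 0.280, against 0.104 and 0.277 in WT-281). Lysate RNA carried into the control TRAP fractions is a candidate explanation. Removing such carry-over left the ribosomal protein difference in normoxia TRAP at 0.641 (0.513 before, SE of the change 0.0778). Rescaling without the 20 most abundant and all mitochondrial genes left it at 0.520 (SE of the change 0.0816). Neither lowered the difference, but the tables argue against both for that part only by this paired SE, chosen after the results were seen. By the unpaired SE of the corrected values (0.285 and 0.268), both would have stayed open. Malat1 was enriched in every control TRAP library (lowest TRAP/input ratio 3.69, SD of the log2 ratio 1.10), which carried-over lysate alone would not give. For the mitochondrial part, carry-over cannot be told apart from a difference of genotype. Fibroblast transcripts, another marker of carry-over, were likewise low in KO-84 and KO-94. They differed in TRAP/input ratio by −0.25 ± 0.31 (SE over genes), against −1.78 for mitochondrial mRNAs, and their spread covers too wide a range. Genotype, the difference the design names, stays open and untested, as do unrecorded differences between purifications.

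A second pattern was the lower inflammatory transcripts of knockout-labelled libraries, beside lower fibroblast transcripts. If fibroblasts in the control cultures were the source, inflammatory transcripts should be depleted in control TRAP as fibroblast transcripts were (−1.13). As a set they were not (mean −0.0149 ± 0.181, SE over 22 genes, which are not independent replicates), but 11 of the 22 were below 0 (SD 0.85). This argues against fibroblasts as the source of the list as a whole. A fibroblast source of part of the list stays open. Genotype remains open, as does any difference between the individual animals, since controls numbered 2.

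The third pattern was Elavl1, lower under hypoxia in input in every animal (mean log2 change −2.35). Noise of single-gene values may give such a fall, since its SD between libraries (1.78) lay at percentile 98.5 of 3015 genes of similar level, of which 252 were lower in every animal. The share of these genes with a mean change as large was 0.000663 (2 of 3015), and 0.0131 (2 of 153) among those with at least its SD within conditions (1.5), which argues against noise alone. In input alone the fall did not pass in limma over the 5 animals (adjusted p = 0.651), and the smallest two-sided sign-test p that 5 animals allow is 0.0625 (exact). An effect of hypoxia stays a hypothesis found and examined on the same data.

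Other splits of the samples were compared with the real ones. For TRAP against input, 3 of 100 splits gave as many genes as the real 102 and 2 of 100 as many lists as the real 10 (highest other 1225 genes and 10 lists). The split with 1225 genes put every library of KO-94 on one side and every library of KO-84 on the other; so large a count points to a structure of the samples, and what it is was not tested. Among splits that part every TRAP and input pair, 1 of 100 did so for genes (highest other 5) and 1 of 100 for lists (highest other 8). These shares assume that the 2 cultures of an animal vary independently. Their deviations from the group means correlated (r = 0.23 to 0.76), so chance is not excluded by them. With fractions exchanged within whole animals, the splits were too few for a share under 0.05: the real counts were 102 genes (highest other 0; 1 of 16 as large) and 10 lists (highest other 8; 1 of 16).

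For the remaining comparisons the splits were too few for a share under 0.05. Where 6 or 7 of 10 splits called at least as many lists, the real count of lists did not stand out from other groupings of the animals or cultures. Under hypoxia in knockout-labelled animals, the real count of genes was 0 in input (highest other 5; 10 of 10 as large), 0 in TRAP (2; 10 of 10) and 0 for the TRAP/input ratio (0; 10 of 10). Lists numbered 5 in input (highest other 11; 7 of 10 as large), 2 in TRAP (9; 7 of 10) and 0 for the ratio (3; 10 of 10). Between genotypes, lists numbered 5 in normoxia input (11; 7 of 10), 6 in hypoxia input (10; 6 of 10), 9 in normoxia TRAP (12; 2 of 10) and 8 in hypoxia TRAP (11; 2 of 10).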

How the results depend on the processing

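Leaving out the single libraries of WT-280 (hypoxia input) and KO-84 (normoxia input), and all averaged fits, were chosen only after the results were seen. The cause of the changes below was not tested, except that leaving out libraries leaves fewer samples.

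Of 741 alternatives for called lists, 493 kept direction and call, 239 lost the call and 9 reversed. Of 2193 for named genes, 2124 kept direction and side of the threshold, 35 no longer passed, 17 newly passed and 17 reversed. Camera does not use the trend, so the 57 of 57 list calls kept by limma without it were fixed in advance and check nothing. They are included in the 741 and the 493. Quantile normalization kept 46 of 57 list calls and the replicate block 26 of 29.

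With an estimated correlation, 0 lists were called in every comparison that had calls (the averaged fit included) except TRAP against input, with 1. fry called 0, except for 2 in TRAP against input.

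Without the filter, genes passing numbered 2 (hypoxia in control input), 1 (genotype in normoxia input), 1 (hypoxia input), 13 (hypoxia in control TRAP), 2 and 10 (genotype in normoxia and hypoxia TRAP), 20 and 2 (change of TRAP/input in controls and knockout-labelled animals), 10 and 18 (genotype difference of TRAP/input in normoxia and hypoxia) and 0 (averaged fit); lists under hypoxia in control input numbered 3. With only the libraries compared, 1 gene passed for hypoxia in control input and 1 for genotype in hypoxia input.

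A pseudocount of 0.1 gave 1 gene in the TRAP interaction, 0 for the change of TRAP/input in controls and 0 in the averaged fit. It called 3 lists under hypoxia in knockout-labelled input, 1 in control TRAP, 6 in TRAP against input and 1 for the genotype difference of TRAP/input in hypoxia. A pseudocount of 5 gave 1 gene for genotype in normoxia TRAP and 1 in hypoxia TRAP, 2 for the change of TRAP/input in controls, 4 for its genotype difference in hypoxia and 0 in the averaged fit. It called 8 lists under hypoxia in knockout-labelled input, 1 in the input interaction, 1 for the genotype difference of TRAP/input in normoxia and 8 in the averaged fit. Quantile normalization gave 61 genes in TRAP against input, 4 for the change in controls, 2 for the genotype difference of TRAP/input in hypoxia and 0 in the averaged fit, and 1 list in the input interaction.

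The replicate block gave 1104 genes in TRAP against input and 1 for the genotype difference of TRAP/input in hypoxia (smallest adjusted p = 0.0226). It ended the erythroid (0.113), class II TRAP (0.0731) and hypoxia mitochondrial TRAP/input (0.0787) calls and no other.

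Leaving out animals or single libraries gave, from lowest to highest, 0 to 1 genes (hypoxia in knockout-labelled input), 0 to 2 (genotype, normoxia input), 0 to 1 and 0 to 2 (genotype, normoxia and hypoxia TRAP), 30 to 81 (TRAP against input), 0 to 3 (change of TRAP/input in controls), 0 to 1 (its genotype difference in hypoxia) and 0 to 0 (averaged fit). Lists called ranged from 1 to 2 and 4 to 8 (hypoxia in control and knockout-labelled input), 4 to 10 and 2 to 7 (genotype in normoxia and hypoxia input), 0 to 2 (input interaction), 0 to 2 in both genotypes (hypoxia, TRAP), 5 to 13 and 3 to 9 (genotype in normoxia and hypoxia TRAP), 0 to 1 (TRAP interaction), 5 to 11 (TRAP against input), 0 to 1 (change of TRAP/input in knockout-labelled animals), and 1 to 2 and 0 to 2 (genotype difference of TRAP/input in normoxia and hypoxia).

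Reversals all came from leaving out samples. Under hypoxia in control input, adjusted p ranged from 0.0345 to 0.937 for oxidative phosphorylation and from 0.138 to 0.979 for ATF4 targets, both reversed without the WT-280 hypoxia library. There, log2 fold changes ranged from −0.36 to 3.89 for Car9 (−0.00154 without that library), −0.0422 to 0.74 for Cycs, −0.13 to 0.63 for Sdhd, −2.92 to 0.11 for Trib3 and −0.54 to 0.0531 for Hif1a. In knockout-labelled input, the mitochondrial adjusted p ranged from 0.00389 to 0.590 (0.534 and reversed without the KO-84 normoxia library), and Vegfa from −0.35 to 0.48. Between genotypes in hypoxia input, oxidative phosphorylation ranged from 0.00246 to 0.997 (0.996 without the WT-280 library), the cell cycle from 1.44e-06 to 0.833 (reversed without WT-280, 0.0929, or its library, 0.129), Ccne2 from −2.53 to 0.26 and Elavl1 from −0.91 to 1.92 (−0.18 without KO-84). In TRAP, the cell cycle ranged from 4.48e-08 to 0.720 in normoxia and 1.12e-09 to 0.325 in hypoxia, and Elavl1 from −0.95 to 2.47 (−0.13 without KO-94) and −0.55 to 1.57 (−0.34 without KO-94). Under hypoxia in TRAP, Vegfa ranged from −0.48 to 0.40 in controls and Tnf from −0.58 to 0.10 in knockout-labelled animals.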

Other observations

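The averaged fits, the 10-pair fit and the ferritin test were chosen only after the results were seen.

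Hypoxia was also compared with normoxia over all 5 animals, averaging the input and TRAP log2 values of each culture. Elavl1 was the 1 gene of 14842 that passed in limma (log2 fold change −2.01 ± 0.207, SE; adjusted p = 0.0427; lower in 5 of 5 animals), with 1001 genes at an unadjusted p under 0.05. This call was lost in each alternative tried for it. The limma adjusted p was 0.0606 with quantile normalization, 0.322 without the filter, and 0.0860 and 0.158 with pseudocounts of 0.1 and 5. It was 0.189 without WT-280, 0.14 without WT-281, 0.431 without KO-84, 0.182 without KO-94 and 0.242 without KO-179. The log2 fold change of Elavl1 in these alternatives ranged from −2.26 to −1.51. The HIF target Ankrd37 (1.87) and the transferrin receptor Tfrc (−2.11 ± 0.332) followed, each with an adjusted p of 0.293 and the same direction in 5 of 5 animals. Fits of input or TRAP alone passed 0 genes in limma (997 and 705 at an unadjusted p under 0.05). In that of input, camera called mitochondrially encoded mRNAs (lower, adjusted p = 0.000227), nuclear oxidative phosphorylation (higher, 0.0134) and the neutrophil list (3 tested genes, higher, 0.0163). None of these 3 was called in the averaged fit. With an estimated correlation they had an adjusted p of 0.572, 0.419 and 0.336. A fit of 10 pairs, which are not independent because the fractions share lysates, passed 5 genes: Ccnl1 (−0.92), Tfrc, Ankrd37 and Fam162a (0.91), each with an adjusted p of 0.0155, and Bnip3 (1.03; 0.0358). There Elavl1 was lower in 9 of 10 pairs (adjusted p = 0.170).

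In the averaged fit camera called 5 lists. HIF targets (0.50; adjusted p = 6.91e-08; 0.203 with an estimated correlation) and glycolysis (0.32; 9.32e-07; 0.248 with an estimated correlation) were higher in 5 of 5 animals, and immediate early genes lower in 5 of 5 (−0.53; 1.9e-07; 0.295 with an estimated correlation). Class II antigen presentation was higher in 4 of 5 (0.49; 7.12e-05; 0.203 with an estimated correlation) and ATF4 targets lower in 4 of 5 (−0.26; 0.00173; 0.59 with an estimated correlation). With 16 ways of exchanging the oxygen labels within animals, the splits were too few for a share under 0.05. As 4 of 16 called at least as many lists, the real count of lists did not stand out. The real count was 1 gene (highest other 0; 1 of 16 as large) and 5 lists (highest other 8; 4 of 16). For input alone and for TRAP alone it was 0 genes (highest other 0; 16 of 16 in each).

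Tfrc fell in every animal in both fractions, in input for example from 29.4 to 1.80 TPM in WT-280 and from 27.6 to 6.15 TPM in KO-179. Lower binding of iron regulatory proteins, which stabilize Tfrc mRNA and repress translation of ferritin mRNAs, could give this. It would also raise the share of ferritin mRNA on ribosomes. The log2 TRAP/input ratio changed under hypoxia by −0.44 (SD 0.230) for Fth1 and −0.54 (SD 0.570) for Ftl1, lower in 5 of 5 animals for each. This argues against it for these ferritin mRNAs only. Slc40a1, the iron exporter gene, went the other way: it changed by −1.13 ± 0.230 in input and by −0.236 ± 0.326 in TRAP (SE). Its TRAP/input ratio was not tested, and beyond the ferritins the explanation stays open.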
